A study of Homo sapiens with 12 samples.

How the data were processed

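RNA sequencing of PEO1, an established human ovarian cancer cell line, was analysed in 12 libraries. Per the labels, cells carried either the pLKO.1 control vector or a short hairpin RNA against p53, and were either untreated at 0 h or exposed to 10 μM fulvestrant for 48 h, with 3 libraries in each of the 4 groups. Cells grew in medium with 10% serum and 2 μg/mL puromycin, and libraries were made from 500 ng of RNA with a stranded mRNA kit and 9 PCR cycles, per the labels' protocols. The treatment protocol names 100 pM estradiol (E2) together with fulvestrant. Whether the untreated cells also received estradiol is not given in the sources used here, and the untreated libraries carry another time point, so a difference between fulvestrant and untreated libraries holds the drug, the time in culture and any difference in estradiol together.

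The deposited table holds estimated counts per gene (RSEM expected counts) as whole numbers, without normalization, per the file headers, the table's title and its values. RSEM 1.3.3, Bowtie2, cutadapt and MultiQC are named in the submitters' processing notes, with GRCh37/hg19 as the genome build. The annotation release, the roles and settings of the tools, whether counting used the strand, and the versions of the last 3 tools are not given in the sources used here. RSEM divides reads that match several transcripts between them, so genes with near-identical copies have less certain counts. The table names genes by symbol and transcript identifiers, and gene names were taken from it as given. Of its 57773 entries, 30146 had 0 counts in all 12 libraries and 211 shared a symbol with another entry. A further 6 columns of per-sample values matched no sample used here and entered no step. No coordinates are printed, because the reference annotation at hand is of another build.

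Counts were analysed in R 4.3.3 with edgeR 4.0.16. Expected counts were rounded to whole numbers, which left the deposited values as they were. Library sizes were scaled by TMM factors, which ranged from 0.98 to 1.06, and genes with low counts were removed by filterByExpr with the 4 groups, leaving 15715 genes. A single model with 1 mean per group was fitted to all 12 libraries by the robust quasi-likelihood method, without covariates. In that model 5 contrasts were tested: knockdown against control vector in untreated and in fulvestrant-treated cells, fulvestrant against untreated in control-vector and in knockdown cells, and the difference between the 2 fulvestrant responses. Adjusted p-values are edgeR quasi-likelihood p-values with Benjamini-Hochberg adjustment over the tested genes of a contrast, with a threshold of 0.05. Levels are CPM, that is counts scaled to a common library size after TMM, given as the mean ± SD of 3 libraries. Fold changes are on the log2 scale. Their standard errors (SE) are approximate values, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They are not estimates of the fitted model, and can be too small where a group has few counts.

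Gene lists, comparisons, tests, the rule for named genes and most alternative settings were fixed before the data were examined. The 21 lists cover estrogen receptor targets, steroid receptors and their coregulators, p53 targets, the mevalonate and cholesterol pathway, G1/S genes, G2/M genes, interferon response, NF-kB-driven inflammatory genes, epithelial-mesenchymal transition, epithelial and ovarian carcinoma markers, the ATF4 and unfolded protein stress response, hypoxia and glycolysis, the BCL2 family, homologous recombination, immediate early genes, transcripts of the mitochondrial genome, ribosomal proteins, replication-dependent histones, and markers of fibroblasts, of leukocytes and of mesothelial and endothelial cells. They were written from general knowledge and not from these samples. Of their 620 members, 618 were in the table. The leukocyte list had 4 tested members, under the minimum of 5, so 20 lists were tested. Each was tested in the 5 contrasts with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, and p-values were adjusted by Benjamini-Hochberg over all 100 tests. Of the 100 tests, 44 passed. With a correlation estimated from the data 11 passed, and with fry, which asks only whether the genes of a list move one way on balance, 51 passed.

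The genes named are ESR1, PGR, GREB1, CDKN1A and MDM2 whatever their values. To these come, in each of the 4 pairwise comparisons, the 6 largest changes in either direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the replicates of the groups. From each list come the 2 members with the largest change among those past the threshold with a mean log2 CPM of at least 1, and 4 members for estrogen receptor and p53 targets. For the difference between the responses, the 6 genes of smallest p in each direction with a mean log2 CPM of at least 3 were taken. Features without a symbol were passed over. Some genes that this rule takes are not reported here.

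Each library held between 21581887 and 28481541 counts. The biological coefficient of variation of the fit was 15.8%. Replicates of a group differed by more than sampling noise in every pair, with chi-square values per degree of freedom from 2.31 to 78.2, so no library was counted as a duplicate. The procedure was tested on simulated counts drawn from the means and library sizes of these samples with 200 changed genes, and with the list of p53 targets raised as a set. Of 100 genes changed by 1 on the log2 scale, 69 were recovered in the knockdown comparison of untreated cells, 74 in that of fulvestrant-treated cells, 68 in the fulvestrant response of control-vector cells, 65 in that of knockdown cells and 61 in the difference between the responses. For a change of 2 these numbers were 88, 92, 93, 89 and 76. Unchanged genes called in these simulations were 11, 12, 10, 16 and 7. Genes were drawn independently of each other there, without the spread along 1 axis that the real libraries have. These numbers may therefore not hold for the real libraries.

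Overlaps of calls are set beside the number expected of independent lists. The knockdown comparison in untreated cells and the fulvestrant response of control-vector cells share their 3 untreated control libraries, so unchanged groups were simulated 20 times against shared controls. Alternatives were DESeq2 size factors and library totals in place of TMM, no low count filter, the DESeq2 1.42.0 Wald test, the replicate number as a block, only the 6 libraries of a comparison, leaving out each of the 12 libraries in turn, a fold change filter, camera with an estimated correlation and fry. A correction for GC content was chosen after the data were seen. It fits each library's log2 deviation from the mean of all 12 libraries by a natural spline with 5 degrees of freedom on transcript GC content, and uses the fit as an offset. It therefore also removes differences between groups that follow GC content, whatever their cause. In simulated counts with the libraries' GC trends planted, 105 of 200 changed genes were recovered for the difference between the responses, with 1 false call. With the correction these were 126 and 7. For knockdown with fulvestrant they were 139 and 3 without it, and 151 and 3 with it. The planted trends were those the correction fits, so errors from another cause of the spread could not show there. GC content was the median over a gene's transcripts, matched by transcript identifier to a later reference transcript set, and 97.8% of the tested genes had a value. Same-numbered libraries of the untreated groups deviated together from their group means (correlations 0.87, 0.18 and 0.81 for numbers 1, 2 and 3), which comes from the data and not from the labels, so the replicate number as a block within the untreated libraries, alone and with the GC content correction, was added after the data were seen. A fit without the 4 libraries, 1 per group, farthest from their group along the GC trend was also chosen after the data were seen. Fisher's exact test, also chosen after the data were seen, compared the signs of estrogen receptor targets lowered by fulvestrant with those of the other targets. Plots were drawn with matplotlib 3.10.9.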

Results

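The transcriptome of PEO1 ovarian cancer cells was measured by RNA sequencing to ask how knockdown of p53, which is mutant in the cells the study concerns, alters estrogen receptor alpha activity and the response to fulvestrant. Fulvestrant is an estrogen receptor antagonist used in endocrine therapy. Control-vector (pLKO.1) and p53-knockdown cells were compared untreated and after 48 h with 10 μM fulvestrant, with 3 libraries in each of the 4 groups. Libraries 1, 2 and 3 held 28481541, 22741703 and 25998712 counts in untreated control-vector cells and 22179665, 22851811 and 22308211 with fulvestrant. In knockdown cells they held 27096698, 23440536 and 25161990 counts untreated and 21950597, 25386239 and 21581887 with fulvestrant. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

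**Figure D1:**
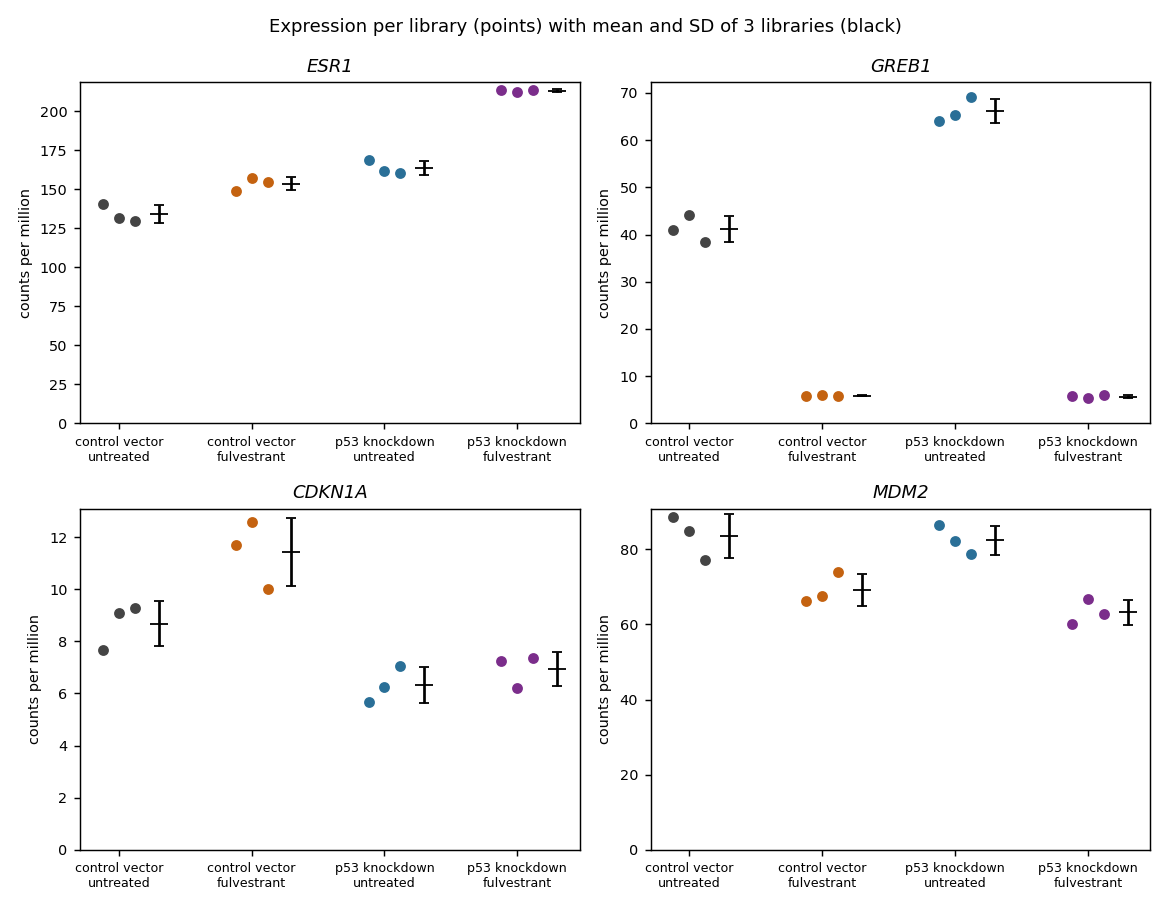
Normalised counts (CPM) of ESR1, GREB1, CDKN1A and MDM2 in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group. GREB1 falls from 41.2 and 66.2 CPM to 5.89 and 5.63 CPM with fulvestrant in control-vector and knockdown cells, and ESR1 lies at 134, 154, 164 and 213 CPM in the 4 groups from left to right.

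The comparison of knockdown with control vector in untreated cells asks what loss of p53 changes before treatment. Estrogen receptor targets were higher in knockdown cells and p53 targets were lower. GREB1 (ENST00000234142), an estrogen-induced gene, rose from 41.2 ± 2.78 to 66.2 ± 2.59 CPM (mean ± SD, n = 3 each), a log2 fold change of 0.68 (SE 0.07, edgeR adjusted p = 0.000358). The dehydrogenase gene DHRS2 rose by 1.32 on the log2 scale, the EGFR ligand gene AREG by 1.06, the carbonic anhydrase gene CA12 (ENST00000178638) by 1.02 and AGR2 by 0.94, with adjusted p-values between 7.52e-05 and 0.00206. Of the 50 tested estrogen receptor targets, 9 rose and 0 fell over all genes tested by edgeR, and 14 rose and 2 fell adjusted over the list alone. The median of the list was 0.12 (camera adjusted p = 4.78e-10), with adjusted p = 0.0193 with an estimated correlation. Transcripts of the mitochondrial genome, a sign of library quality, had a larger median of 0.23 in this comparison (camera adjusted p = 0.000419), with adjusted p = 0.51 with an estimated correlation.

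Among p53 targets, ZMAT3 (ENST00000311417), which encodes a zinc finger RNA-binding protein, fell from 30.9 ± 1.47 to 11.6 ± 0.804 CPM (log2 fold change −1.41, SE 0.07, edgeR adjusted p = 6.62e-06), and RPS27L (ENST00000330964) fell from 24.9 ± 1.41 to 10.1 ± 0.526 CPM (−1.29, SE 0.11, adjusted p = 0.000191). DDB2, a DNA damage recognition gene, had a log2 fold change of −0.58 (adjusted p = 0.00815), a call lost without untreated control-vector library 2 (adjusted p = 0.0514) or untreated knockdown library 1 (adjusted p = 0.0502). Of 38 tested p53 targets, 3 fell and 0 rose, or 7 and 1 adjusted over the list alone. Their median was −0.14 (camera adjusted p = 1.92e-05), with adjusted p = 0.0296 with an estimated correlation. CDKN1A (ENST00000244741), which encodes the cell cycle inhibitor p21, had a log2 fold change of −0.46 (adjusted p = 0.146), and MDM2 (ENST00000258148), which encodes the p53 ubiquitin ligase, one of −0.02 (adjusted p = 1).

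ESR1 (ENST00000206249), the gene of estrogen receptor alpha, stood at 134 ± 5.79 CPM in untreated control-vector cells and at 164 ± 4.34 CPM in untreated knockdown cells (log2 fold change 0.29, SE 0.05, edgeR adjusted p = 0.00866). This call was lost without untreated control-vector library 2 (adjusted p = 0.0639), without untreated knockdown library 1 (0.053) and without the low count filter (0.0691). PGR (ENST00000263463), the progesterone receptor gene, had between 0 and 6 counts per library and was not tested.

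The remaining large changes in untreated knockdown cells included higher levels of the transcriptional repressor gene BHLHE41 (log2 fold change 1.38), TNS4 (1.24), the heparan sulfatase gene SULF2 (1.19), the metalloproteinase inhibitor gene TIMP3 (1.06) and the mTOR inhibitor gene DEPTOR (ENST00000286234, 1.04). ESM1 (−1.46), NEGR1 (−1.19) and the growth factor gene FGF5 (−0.97) fell, all of these with edgeR adjusted p-values of 0.00171 or lower. Of 26 epithelial-mesenchymal transition genes, 4 rose and 1 fell, or 9 and 2 adjusted over the list alone (median 0.13, camera adjusted p = 0.00531). For this list adjusted p = 0.257 with an estimated correlation. After the GC content correction 5 rose and 3 fell over all genes, with adjusted p = 0.0555 with an estimated correlation. VIM, which encodes the intermediate filament vimentin, rose from 8.75 ± 0.748 to 17.5 ± 0.85 CPM (adjusted p = 0.000198). Of 38 interferon response genes, 2 fell and 0 rose, or 5 and 0 adjusted over the list alone (median −0.13, camera adjusted p = 8.91e-09), with adjusted p = 0.0769 with an estimated correlation, or 0.0162 after the GC content correction chosen after the data were seen. The interferon-induced gene MX1 fell by 0.59 on the log2 scale (adjusted p = 0.00171). INSIG1, a regulator of sterol synthesis, fell by 0.74 (adjusted p = 0.000198).

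In all, 249 genes differed between knockdown and control vector in untreated cells, 160 higher and 89 lower, of which 34 changed by at least 1 on the log2 scale. The count was 189, 126 and 149 without untreated control-vector library 1, 2 or 3, and 133, 127 and 151 without untreated knockdown library 1, 2 or 3. It was 1007 after the GC content correction, with 522 higher and 485 lower, so the excess of higher genes was smaller there.

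With fulvestrant, the comparison of knockdown with control vector asks whether the treated cells still differ. G1/S genes were lower in treated knockdown cells than in treated control-vector cells. Of 36 G1/S genes, 28 fell and 0 rose over all genes, and all 36 fell adjusted over the list alone, with a median log2 fold change of −0.52 (camera adjusted p = 8.2e-30). For this list adjusted p = 0.00923 with an estimated correlation. In the same comparison transcripts of the mitochondrial genome had a median of 0.31 and replication-dependent histones one of −0.98 (camera adjusted p-values 0.000204 and 0.00991, with adjusted p = 0.483 and 0.646 with an estimated correlation). CHAF1A, a chromatin assembly gene, stood at 42.1 ± 7.68 CPM in treated control-vector cells and at 26.4 ± 4.14 CPM in treated knockdown cells (log2 fold change −0.67, SE 0.14, edgeR adjusted p = 0.0167), with adjusted p = 0.112 in a fit of only the 6 libraries. Of 30 homologous recombination genes 13 fell and 0 rose, or 20 and 0 adjusted over the list alone (median −0.35, camera adjusted p = 1.52e-12), with adjusted p = 0.127 with an estimated correlation. RAD54L, a recombination helicase gene, fell from 31.5 ± 0.783 to 21.4 ± 1.2 CPM (adjusted p = 0.000888). Of 36 G2/M genes 11 fell and 0 rose, or 20 and 0 adjusted over the list alone (median −0.22, camera adjusted p = 3.03e-12), with adjusted p = 0.205 with an estimated correlation. The recombination and G2/M lists passed with an estimated correlation after the GC content correction (adjusted p = 0.00104 and 0.00229). Across genes, the log2 fold changes of this comparison correlated with transcript GC content at a Spearman rho of −0.41, against −0.18 for the comparison of untreated cells.

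The p53 targets were lower in treated knockdown cells as well, with 9 fallen and 2 risen, or 13 and 3 adjusted over the list alone (median −0.21, camera adjusted p = 0.000103). For this list adjusted p = 0.0443 with an estimated correlation. RPS27L fell by 1.37, ZMAT3 by 1.29 and DDB2 by 0.95 on the log2 scale (edgeR adjusted p-values 0.00012, 9.27e-06 and 0.000261). BAX was also lower, at −0.67 after the GC content correction (adjusted p = 2.41e-06). It lost its call with the replicate number as a block in untreated cells alone (−0.9, adjusted p = 0.0591). CDKN1A fell from 11.4 ± 1.3 to 6.94 ± 0.645 CPM (log2 fold change −0.72, SE 0.13, adjusted p = 0.00666), and MDM2 had a log2 fold change of −0.13 (adjusted p = 0.321). After the GC content correction these were −0.51 and −0.20 (adjusted p-values 0.0421 and 0.00127), and with the replicate number as a block in untreated cells beside that correction CDKN1A lost its call (adjusted p = 0.0792).

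Estrogen receptor targets went both ways in treated cells. In knockdown against control-vector cells 6 rose and 3 fell, or 9 and 5 adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.415). AGR2 rose from 7.67 ± 0.931 to 19.2 ± 0.265 CPM (log2 fold change 1.32), RERG rose by 1.03 and DHRS2 by 0.91, with edgeR adjusted p-values of 0.000105, 0.000405 and 0.000443. GREB1 stood at 5.89 ± 0.123 and 5.63 ± 0.324 CPM in the 2 lines (log2 fold change −0.07, adjusted p = 0.695). The cyclin D1 gene CCND1 had a log2 fold change of −0.49 (adjusted p = 0.00588), which was −0.19 (adjusted p = 0.709) after the GC content correction and had adjusted p = 0.0674 in a fit of only the 6 libraries. ESR1 was higher in treated knockdown cells, at 213 ± 0.996 against 154 ± 4.24 CPM (log2 fold change 0.47, SE 0.05, adjusted p = 0.000244). Among 22 steroid receptors and coregulators 7 rose and 0 fell, also adjusted over the list alone, with ESR1 among them (median 0.17, camera adjusted p = 0.000419). Here adjusted p = 0.0534 with an estimated correlation.

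Other genes higher in treated knockdown cells were BHLHE41 (log2 fold change 1.56), C12orf36 (1.37), the immune checkpoint ligand gene VTCN1 (1.23), LIMCH1 (1.15), VIM (1.11) and MUC16 (ENST00000380951), which encodes the CA125 antigen (0.95). ESM1 (−1.58) and the dendritic cell and lymphocyte surface marker gene CD83 (−1.21) were lower, all with edgeR adjusted p-values of 0.00102 or less. TNS4 (1.08) and the kisspeptin gene KISS1 (−1.74) each had an adjusted p of 0.00297, and lost their calls in a fit of only the 6 libraries (adjusted p = 0.0862 and 0.0577). Of 24 NF-kB-driven inflammatory genes 3 fell and 0 rose, or 8 and 0 adjusted over the list alone (median −0.23, camera adjusted p = 2.58e-05), with adjusted p = 0.0513 with an estimated correlation. The chemokine gene CXCL1 fell from 31.2 ± 2.07 to 20.8 ± 0.531 CPM (adjusted p = 0.000443).

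In all, 1103 genes differed between the treated lines, 672 higher and 431 lower, and 106 of them by at least 1 on the log2 scale. The count was 673, 456 and 2270 without fulvestrant-treated control-vector library 1, 2 or 3, and 466, 538 and 552 without fulvestrant-treated knockdown library 1, 2 or 3. It was 229 in a fit of only the 6 libraries, and 3189 after the GC content correction, with 1384 higher and 1805 lower.

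**Figure D2:**
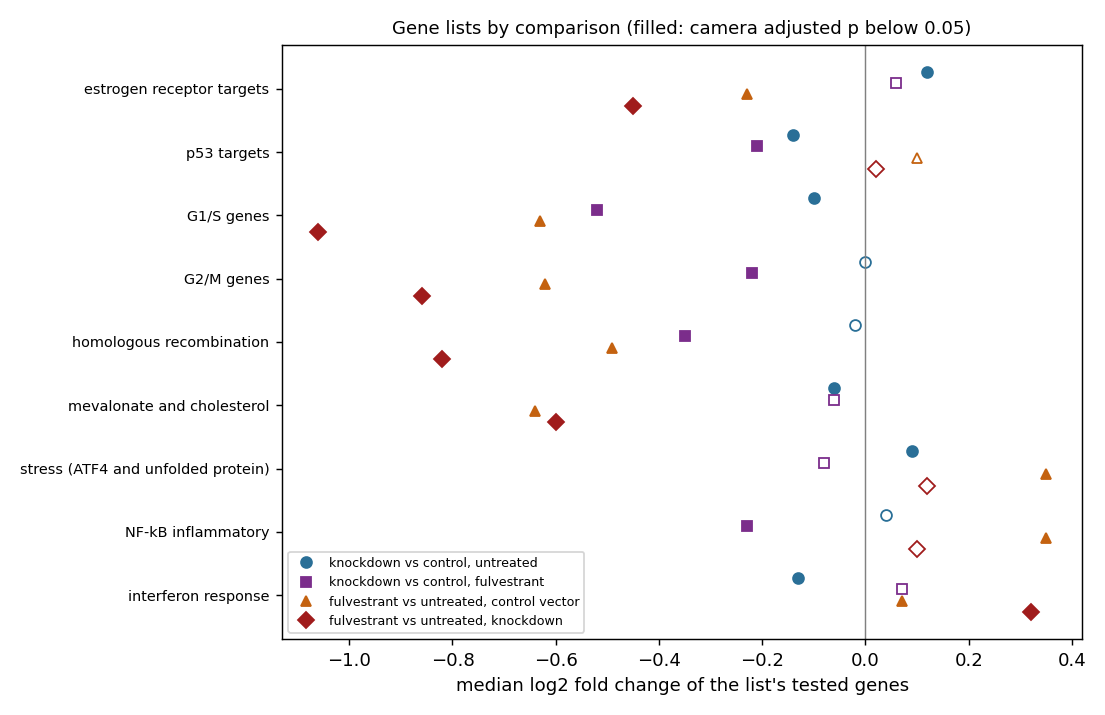
Median log2 fold change of the tested members of 9 gene lists in the 4 pairwise comparisons, with filled symbols where the camera adjusted p was below 0.05. G1/S genes have medians of −0.63 and −1.06 with fulvestrant in control-vector and knockdown cells, and estrogen receptor targets have medians of 0.12 with knockdown in untreated cells and −0.23 and −0.45 with fulvestrant.

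Fulvestrant against untreated in control-vector cells gives the response to treatment where p53 was left in place. The lists of estrogen receptor targets, sterol synthesis genes, G1/S genes and G2/M genes were lower and that of stress response genes was higher. With an estimated correlation the estrogen receptor and G2/M lists lost their calls (adjusted p = 0.0513 and 0.0851) and the others kept them. GREB1 fell from 41.2 ± 2.78 to 5.89 ± 0.123 CPM (log2 fold change −2.80, SE 0.07, edgeR adjusted p = 6.27e-09). CA12 fell from 27.2 ± 2.49 to 0.321 ± 0.0837 CPM (−6.38, edgeR adjusted p = 1.86e-08), a treated level too low for the approximate SE. The cytokine signalling inhibitor gene CISH fell by 2.62 and DHRS2 by 2.42 on the log2 scale. Of 50 estrogen receptor targets 18 fell and 5 rose, or 20 and 5 adjusted over the list alone (median −0.23, camera adjusted p = 3.89e-05), with adjusted p = 0.0513 with an estimated correlation. The mRNA of the receptor itself, ESR1, had a log2 fold change of 0.20 (SE 0.05, adjusted p = 0.00834), a call lost without fulvestrant-treated control-vector library 2 (adjusted p = 0.0528), without the low count filter (0.0755) and in a fit of only the 6 libraries (0.075).

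Of 24 mevalonate and cholesterol genes 17 fell and 0 rose, or 18 and 0 adjusted over the list alone (median −0.64, camera adjusted p = 8.58e-10). For this list adjusted p = 0.0296 with an estimated correlation. ACAT2 fell from 89.9 ± 9.14 to 46.5 ± 3.61 CPM and EBP, a sterol isomerase gene, from 94.6 ± 3.86 to 51.9 ± 0.801 CPM (edgeR adjusted p-values 2.67e-05 and 5.52e-06). Of 36 G1/S genes 32 fell and 0 rose, or 34 and 0 adjusted over the list alone (median −0.63, camera adjusted p = 1.56e-18), with adjusted p = 0.0193 with an estimated correlation. The replication factor gene MCM10, a member, fell from 61.3 ± 4.76 to 34 ± 2.96 CPM (log2 fold change −0.85, adjusted p = 2.92e-05). All 36 G2/M genes fell, also adjusted over the list alone (median −0.62, camera adjusted p = 5.78e-22), with adjusted p = 0.0851 with an estimated correlation. The mitotic kinase gene AURKA fell from 125 ± 9.46 to 69.9 ± 3.13 CPM and the centromere histone gene CENPA from 34.7 ± 2.74 to 19.9 ± 2.55 CPM. Of 30 homologous recombination genes 20 fell and 0 rose, or 22 and 0 adjusted over the list alone (median −0.49, camera adjusted p = 2.55e-08), with adjusted p = 0.227 with an estimated correlation. The exonuclease gene EXO1 and the end resection gene RBBP8 each had a log2 fold change of −0.74 (adjusted p-values 2.92e-05 and 6.81e-05). With an estimated correlation the estrogen receptor, G2/M and recombination lists passed after the GC content correction (adjusted p = 0.022, 0.00171 and 0.00271).

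Of 35 stress response genes 19 rose and 1 fell with fulvestrant in control-vector cells, or 20 and 3 adjusted over the list alone (median 0.35, camera adjusted p = 2.58e-05). For this list adjusted p = 0.0296 with an estimated correlation. The transcription factor gene DDIT3, which encodes CHOP, rose from 10.3 ± 0.868 to 21.8 ± 2.84 CPM (log2 fold change 1.09, edgeR adjusted p = 8.83e-05), and NUPR1 rose by 1.51 (adjusted p = 0.00824). Of 24 NF-kB-driven genes 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (median 0.35, camera adjusted p = 0.000422), with adjusted p = 0.0851 with an estimated correlation. The last value was 0.0446 after the GC content correction. The cytokine gene IL6 rose by 1.34 and the prostaglandin synthase gene PTGS2 by 1.56 on the log2 scale. Of 38 interferon response genes 14 rose and 2 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.0185), with adjusted p = 0.483 with an estimated correlation. That camera call was lost without fulvestrant-treated control-vector library 3 (adjusted p = 0.0668), and without the 4 libraries farthest along the GC trend. IFIT2 rose from 16.2 ± 1.79 to 32.4 ± 3.09 CPM. Of 38 p53 targets 11 rose and 4 fell, also adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.11). TP53INP1 was higher and AEN lower, with log2 fold changes of 1.34 and −0.78 after the GC content correction (edgeR adjusted p-values 1.35e-07 and 0.00016). CDKN1A had a log2 fold change of 0.40 (adjusted p = 0.0348), lost without any of the 3 untreated control-vector libraries, fulvestrant-treated control-vector library 1 or 2, untreated knockdown library 2 or fulvestrant-treated knockdown library 1 (adjusted p up to 0.129), without the low count filter (0.0502) and in a fit of only the 6 libraries (0.111). MDM2 had a log2 fold change of −0.27 (adjusted p = 0.0145), lost without untreated or fulvestrant-treated control-vector library 1 or 2 (adjusted p up to 0.115), and with library totals (0.0539).

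Among the largest changes with fulvestrant in control-vector cells were rises of the thioredoxin-interacting protein gene TXNIP (ENST00000369317, log2 fold change 2.08), MUC16 (1.89), the claudin gene CLDN16 (1.70), the protease inhibitor genes SLPI (1.69) and SERPINE2 (1.69) and CTGF (1.67), and falls of DEPTOR (−4.66), the Ras-related gene DIRAS3 (−4.12) and the potassium channel gene KCNF1 (−2.81), beside GREB1, CISH and DHRS2, among genes of a mean log2 CPM of at least 3. DEPTOR went from 49.7 ± 2.33 to 1.96 ± 0.0931 CPM. In all, 2112 genes were higher and 2251 lower with fulvestrant in these cells (4363 in total), and 439 changed by at least 1 on the log2 scale. The count was 6818 after the GC content correction.

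In knockdown cells the lists of estrogen receptor targets, sterol synthesis genes, G1/S genes and G2/M genes were lower with fulvestrant as well, of which only the G1/S list passed with an estimated correlation (adjusted p = 0.0507, 0.0513, 0.0193 and 0.088). Of 36 G1/S genes 35 fell and 0 rose over all genes, and all 36 fell adjusted over the list alone (median −1.06, camera adjusted p = 2.24e-21). The thymidine kinase gene TK1 fell by 1.49 and the chromatin regulator gene UHRF1 from 111 ± 14.4 to 38.4 ± 8.89 CPM (edgeR adjusted p-values 0.0119 and 0.000819). All 36 G2/M genes fell, also adjusted over the list alone (median −0.86, camera adjusted p = 6.28e-21), with adjusted p = 0.088 with an estimated correlation. The mitotic kinase gene AURKB fell from 52.4 ± 2.16 to 21.3 ± 2.3 CPM and PLK1 from 156 ± 6.32 to 73.5 ± 8.97 CPM. Of 30 homologous recombination genes 23 fell and 0 rose, or 25 and 0 adjusted over the list alone (median −0.82, camera adjusted p = 7.48e-11), with adjusted p = 0.166 with an estimated correlation. RBBP8 fell by 1.23 and XRCC3 by 1.37 on the log2 scale. The G2/M, recombination, estrogen receptor and sterol synthesis lists passed with an estimated correlation after the GC content correction (adjusted p = 0.00193, 0.00169, 0.022 and 0.021).

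Estrogen receptor targets fell in treated knockdown cells, 25 of 50 with 7 risen, or 27 and 7 adjusted over the list alone (median −0.45, camera adjusted p = 1.4e-05), with adjusted p = 0.0507 with an estimated correlation. GREB1 fell from 66.2 ± 2.59 to 5.63 ± 0.324 CPM (log2 fold change −3.55, SE 0.07, edgeR adjusted p = 6.55e-10), and CA12 by 6.36 on the log2 scale. ESR1 rose from 164 ± 4.34 to 213 ± 0.996 CPM (0.38, SE 0.05, adjusted p = 7.55e-05). Of 24 mevalonate and cholesterol genes 17 fell and 0 rose, also adjusted over the list alone (median −0.60, camera adjusted p = 8.53e-07), with adjusted p = 0.0513 with an estimated correlation. ACAT2 fell by 1.02 and the mevalonate kinase gene MVK by 1.05. Of 38 interferon response genes 21 rose and 3 fell, or 23 and 3 adjusted over the list alone (median 0.32, camera adjusted p = 9.19e-05), with adjusted p = 0.205 with an estimated correlation. IFIT2 rose from 14.5 ± 1.1 to 44.2 ± 4.38 CPM and TRIM22 by 1.34 on the log2 scale. Of 35 stress response genes 14 rose and 4 fell, also adjusted over the list alone (median 0.12, camera adjusted p = 0.155), with NUPR1 higher by 1.28 and the amino acid transporter gene SLC7A5 lower, at −1.51. Of 24 NF-kB-driven genes 8 rose and 4 fell, also adjusted over the list alone (median 0.10, camera adjusted p = 0.455), with IL6 higher by 1.25. Of 38 p53 targets 11 rose and 6 fell, also adjusted over the list alone (median 0.02, camera adjusted p = 0.541). TP53INP1 was higher and AEN lower here too, with log2 fold changes of 2 and −1.32 after the GC content correction (edgeR adjusted p-values 1.78e-09 and 1.73e-06). ZMAT3 rose by 0.78 and MDM2 fell by 0.38 (adjusted p-values 1.05e-05 and 0.00133), and CDKN1A had a log2 fold change of 0.13 (adjusted p = 0.421), or 0.46 (adjusted p = 0.0327) after the GC content correction.

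TXNIP (2.66), MUC16 (2.34), the apoptosis regulator gene BMF (2.01), the collagen gene COL8A1 (1.86) and SLPI (1.82) were among the genes that rose most in treated knockdown cells, and DEPTOR (−4.88), DIRAS3 (−4.42), KCNF1 (−4.34), DHRS2 (−2.83) and TNS4 (−2.54) fell most beside GREB1, on the log2 scale and among genes of a mean log2 CPM of at least 3. In all, 3351 genes were higher and 3080 lower (6431 in total), 1051 of them by at least 1. Of the genes called in control-vector cells, 1937 were also higher and 2044 also lower in knockdown cells, against 450.4 and 441.2 expected of independent lists, while 2 went opposite ways. Across genes the 2 responses, which share no library, correlated with Pearson's r of 0.76 and Spearman's rho of 0.82, as a description, since genes are not independent replicates. Without the low count filter, which adds genes with few counts, r was 0.21. The 2 knockdown comparisons correlated with r of 0.40 and rho of 0.45 and shared 123 higher and 66 lower genes, against 6.8 and 2.4 expected of independent lists. Their r was 0.18 without untreated control-vector library 3 and 0.25 without untreated knockdown library 1, and 0.07 without the low count filter. That filter was rerun on the libraries left in each fit, so the tested genes changed as well. The fall of r therefore cannot be laid to the library alone.

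The difference between the 2 fulvestrant responses asks whether knockdown altered the response. Of the 4363 genes called in control-vector cells, 99.5% had the same sign in knockdown cells, and 74.7% of these had a larger change there, with median absolute log2 fold changes of 0.45 and 0.55. G1/S genes fell further in knockdown cells. The list had a median difference of −0.40 (camera adjusted p = 7.59e-31), with adjusted p = 0.00923 with an estimated correlation. No single member passed over all genes in edgeR, and 28 of 36 were lower adjusted over the list alone. The replication genes CDC45 (ENST00000263201, −0.52), GINS4 (ENST00000276533, −0.57) and POLA2 (−0.44) were among the smallest p-values, with edgeR adjusted p-values of 0.103, 0.0932 and 0.0932, and passed after the GC content correction (0.00122, 0.00056 and 0.000641). CDC45 went from 69.7 ± 1.41 to 40.6 ± 2.44 CPM in control-vector cells and from 69.1 ± 3.1 to 28 ± 0.783 CPM in knockdown cells. Of 30 homologous recombination genes 14 were lower adjusted over the list alone and none over all genes (median −0.35, camera adjusted p = 2.67e-15), with adjusted p = 0.088 with an estimated correlation. No G2/M gene passed, also adjusted over the list alone, and the list had a median of −0.20 (camera adjusted p = 1.65e-13), with adjusted p = 0.181 with an estimated correlation. Over all genes, 25 G1/S, 15 recombination and 23 G2/M genes were lower after the GC content correction, and the recombination and G2/M lists passed with an estimated correlation as well (adjusted p = 0.000688 and 0.00169). Log2 differences between the responses correlated with transcript GC content across genes at a Spearman rho of −0.37.

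Stress response genes and NF-kB-driven genes rose less with fulvestrant in knockdown cells as lists, with median differences of −0.20 and −0.30 (camera adjusted p-values 1.03e-05 and 1.8e-07). For each of these lists adjusted p = 0.0296 with an estimated correlation, and no single member passed, also adjusted over the list alone. Interferon response genes had a median difference of 0.20, with no member past the threshold over all genes and 5 higher adjusted over the list alone (camera adjusted p = 4.26e-07), with adjusted p = 0.1 with an estimated correlation. Among single members over all genes, 8 stress response and 5 NF-kB-driven genes were lower after the GC content correction, and 4 interferon response genes higher and 1 lower, with adjusted p = 0.028 with an estimated correlation for the last list. Estrogen receptor targets had a median difference of −0.16, with GREB1 lower over all genes and 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 3.89e-05), with adjusted p = 0.0513 with an estimated correlation. That median was −0.05 after the GC content correction (camera adjusted p = 0.0184), with 10 members lower and 1 higher over all genes. The p53 targets had a median difference of −0.05 (camera adjusted p = 0.374).

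Single genes that differed between the responses by edgeR were 4. GREB1 fell further in knockdown cells (difference −0.75, SE 0.10, adjusted p = 0.0478), from a higher untreated level to a like treated one. SH3KBP1 (ENST00000379697, −0.60, SE 0.06, adjusted p = 0.0265) went from 66.8 ± 1.04 to 55.5 ± 0.784 CPM in control-vector cells and from 97.1 ± 3.62 to 53.4 ± 1.08 CPM in knockdown cells. The vitamin D hydroxylase gene CYP24A1 (ENST00000216862, 0.80, SE 0.09, adjusted p = 0.0277) went from 50.4 ± 3.22 to 56.4 ± 4.18 CPM and from 40.7 ± 0.636 to 79.2 ± 1.25 CPM, and the cadherin gene CDH6 (ENST00000265071, 0.62, SE 0.08, adjusted p = 0.0478) from 29.4 ± 1.43 to 57.1 ± 3.23 CPM and from 24.7 ± 0.56 to 73.6 ± 0.91 CPM. Of the other genes of smallest p, SLC43A3 (−0.54), TGFBI (0.46), CCDC80 (0.51), IGFBP3 (0.47) and CD24P4 (0.50), whose reads may be shared with CD24, had adjusted p-values from 0.0932 to 0.109, and all 5 passed after the GC content correction (0.000347 to 0.0394). The differences were 0.18 for ESR1, −0.26 for CDKN1A and −0.11 for MDM2 (adjusted p-values 0.464, 0.859 and 0.917), and 0.15, −0.09 and −0.17 after the GC content correction, where ESR1 passed (adjusted p-values 0.0404, 0.899 and 0.0811). With 1 library left out, edgeR called 7 genes without fulvestrant-treated control-vector library 3, 1 without untreated knockdown library 3 and 0 without any other library, where 884 to 1271 genes had an unadjusted p under 0.05. GREB1 lost its call in all 12 such fits, CDH6 and CYP24A1 in 11 and SH3KBP1 in 10 (adjusted p up to 0.346). All 4 were also lost with library totals, without the low count filter or with the replicate number as a block in untreated cells (adjusted p-values 0.0745 to 0.107 with the block, where edgeR called 0 genes and 1280 had an unadjusted p under 0.05). DESeq2 called 45 genes with all libraries, these 4 among them, and edgeR 597 after the GC content correction.

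**Figure D3:**
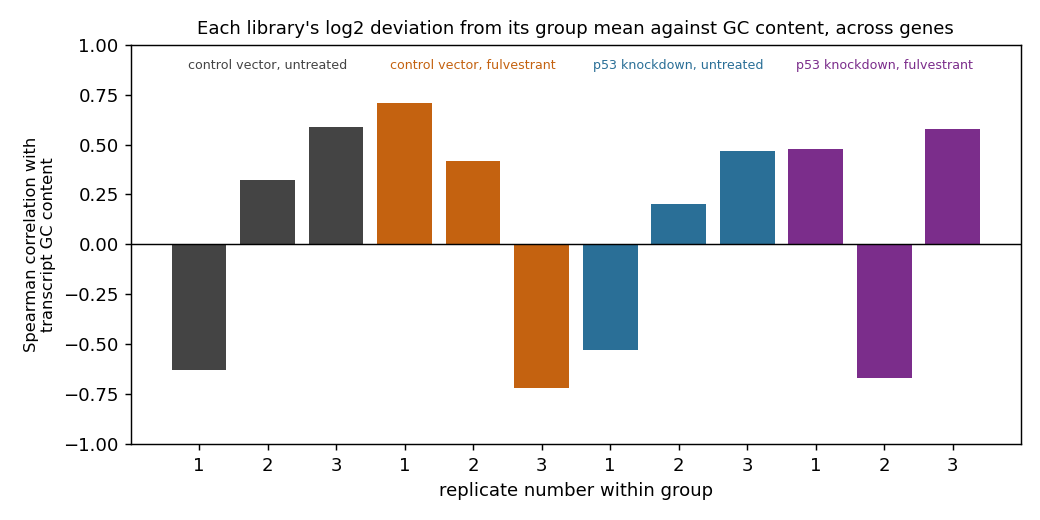
Spearman correlation across genes between transcript GC content and each library's log2 deviation from the mean of its group, for the 12 libraries. In each group 1 library lies between −0.72 and −0.53 and the other 2 lie between 0.20 and 0.71.

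Because the series asks about estrogen receptor activity, genes that changed with knockdown in untreated cells were set beside the fulvestrant response of control-vector cells. Of the genes lowered by fulvestrant, 50 were higher and 23 lower with knockdown, against 22.9 and 12.7 expected of independent lists. Of the genes raised by fulvestrant, 57 were higher and 25 lower with knockdown, against 21.5 and 12 expected. Every combination of directions thus exceeded the number expected, which takes all genes as equally likely to be called. The excess alone therefore cannot show that knockdown and fulvestrant act on the same genes. The number lowered by fulvestrant and higher with knockdown was 26 and 28 without untreated control-vector library 2 or 3, and 31 without untreated knockdown library 1 or 2. After the GC content correction 168 genes lowered by fulvestrant were higher and 173 lower with knockdown, against 123.7 and 115 expected. Both comparisons use the same 3 untreated control-vector libraries, too few to split, which moves genes the same way in both, so part of the excess in the same direction may come from the shared controls. Across genes the fold changes of both comparisons correlated with r of 0.25 against a simulated mean of 0.493, and their covariance was 0.0390 against 0.0423 in simulation (0.0353 to 0.0536). The simulated groups did not differ at all, while real fold changes add variance, so these values of r cannot be compared. Simulated overlaps were 0 in every direction, with a mean of 0.1 genes called with knockdown. They therefore give no expected number for the overlaps. Of the 18 estrogen receptor targets lowered by fulvestrant, 16 had a positive knockdown log2 fold change in untreated cells, with a median of 0.20, and 6 were called higher. Of the other 32 targets 20 had a positive value, with a median of 0.10 (Fisher's exact test between both sets, chosen after the data were seen, p = 0.0563). In treated cells 9 of the 18 had a positive knockdown log2 fold change, with a median of −0.02.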

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

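The tests of what lies behind the spread between replicates, the GC content correction, the block in untreated cells, the fit without 4 libraries and Fisher's exact test were chosen after the result was seen. The other tests were planned or written down before their result was seen. All results in this part concern a difference between the fulvestrant responses of control-vector and knockdown cells, tested as such, or the patterns that bear on it.

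G1/S genes fell further with fulvestrant in knockdown than in control-vector cells, with a median difference of −0.40 over 36 genes. The tables argue against uneven GC content bias as the whole cause, because the median was −0.44 after the GC content correction, and against a single library, since the median nearest to 0 with 1 library left out was −0.37. The part of the within-group axis that this correction leaves was not tested for the list. A biological difference between the lines, such as a stronger cell cycle arrest after loss of p53, may remain as a hypothesis, although it was found and tested on the same data. CDKN1A, which encodes the cell cycle inhibitor p21, was lower in treated knockdown cells. After the GC content correction its log2 fold change was −0.51 (edgeR adjusted p = 0.0421, or 0.0792 with the block in untreated cells beside it). Cell cycle phase, cell density and the time or estradiol difference between treated and untreated cells were not measured, so they stay open.

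Estrogen receptor targets were higher with knockdown in untreated cells, and their median response to fulvestrant differed by −0.16 (camera adjusted p = 3.89e-05, with adjusted p = 0.0513 with an estimated correlation). That difference was −0.05 after the GC content correction (camera adjusted p = 0.0184, with adjusted p = 0.0387 with an estimated correlation), so GC content bias stays open for a part of it. For the knockdown comparison the camera adjusted p was 1.35e-09 after the GC content correction, or 5.53e-09 with the replicate number as a block in untreated cells beside it, and the lowest median with 1 of the 6 libraries left out was 0.11, so neither GC bias nor 1 library is the whole cause. If knockdown acted against fulvestrant on these genes, those lowered by fulvestrant should be higher with knockdown, and 88.9% of the 18 were positive. The list as a whole was higher, so the comparison that bears on this is with its other members, of which 20 of 32 were positive (Fisher's exact test, p = 0.0563). An effect on the members that fulvestrant lowers cannot be told apart from a rise of the list as a whole, because these members are few. Over all genes lowered by fulvestrant, 50 were higher and 23 lower with knockdown against 22.9 and 12.7 expected of independent lists, and 168 and 173 against 123.7 and 115 after the GC content correction, so both directions exceeded that number. Both comparisons share their untreated control-vector libraries, which the number expected of independent lists does not allow for. That number also takes all genes as equally likely to be called, so the excess in opposite directions is no evidence of opposed effects. That p53 in these cells holds back estrogen receptor targets while they are untreated may remain as a hypothesis from the rise of the list, while effects of the hairpin other than on p53 were not tested.

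Within the groups, libraries spread along 1 axis that held 57.9% of the within-group variance, against 7.4% for the next axis. Transcript length explained 0.5% of its loadings, and libraries with the same number did not move together over the 4 groups (lowest correlation −0.93), which argues against RNA length effects and a batch tied to the number in all groups. Between the untreated groups alone every same-numbered pair moved together (lowest correlation 0.18, or 0.07 after the GC content correction), so a batch of untreated libraries may hold a part of the axis. Number 2 did not pair best with itself, though. Untreated control-vector library 2 correlated at 0.55 with untreated knockdown library 3, and untreated knockdown library 2 at 0.23 with untreated control-vector library 3. These pairs alone therefore cannot show such a batch. GC content explained 58.3% of the loadings, but after the correction the first axis still held 37.2% of the variance that was left, or 24.5% of the variance before. The fall passed the bound set for this test counted on the variance before, and missed it counted on the variance left. GC bias in library preparation is therefore a candidate explanation that cannot be told apart from another cause that follows GC content, because these counts disagree and the correction leaves a part of the axis. No biological explanation was tested.

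The single genes that differed between the responses were CDH6 (0.62), CYP24A1 (0.80), GREB1 (−0.75) and SH3KBP1 (−0.60), each called by edgeR. Among 100 of the 200 splits of the libraries that were drawn, 5 gave as many genes as the real one (4 genes), itself included, so chance cannot be excluded. The highest other split gave 3978 genes, which points to a structure of the samples, and it set the libraries low along the GC trend on opposite sides in untreated and treated cells. The remaining 3 kept the fulvestrant libraries apart by line, and so hold the knockdown difference of treated cells. After the GC content correction 8 of 100 splits, the real one included, gave as many as the real one (597 genes). Of the 7 others, 6 kept the fulvestrant libraries apart by line, and so hold the knockdown difference of treated cells. The highest was 1428, or 1079 among those that did not keep the fulvestrant libraries apart by line. Chance could not be excluded there either, since splits that hold a real difference cannot measure chance alone.

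The other lists that differed were G2/M genes with a median difference of −0.20, homologous recombination with −0.35 and interferon response with 0.20, which lost their calls with an estimated correlation (adjusted p = 0.181, adjusted p = 0.088 and adjusted p = 0.1) but passed so after the GC content correction (adjusted p = 0.00169, adjusted p = 0.000688 and adjusted p = 0.028), NF-kB-driven genes with −0.30 and stress response with −0.20, which kept them (adjusted p = 0.0296 each), and steroid receptors and coregulators with 0.12 (camera adjusted p = 0.00238, with adjusted p = 0.0851 with an estimated correlation, or 0.0197 after the GC content correction). Immediate early genes had −0.17 (camera adjusted p = 0.0149, with adjusted p = 0.646 with an estimated correlation), a call lost without untreated control-vector library 1, fulvestrant-treated control-vector library 1, untreated knockdown library 2 or fulvestrant-treated knockdown library 2 (adjusted p up to 0.218), and after the GC content correction, which moved the median to −0.05 (adjusted p = 0.223). Ribosomal proteins had 0.07 (camera adjusted p = 0.0478, with adjusted p = 0.672 with an estimated correlation), a call lost in 7 of the 12 fits with 1 library left out, namely without untreated control-vector library 1 or 2, fulvestrant-treated control-vector library 1 or 3, untreated knockdown library 3 or fulvestrant-treated knockdown library 1 or 3 (adjusted p up to 0.273).

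In each of the 4 pairwise comparisons 6 libraries allow 10 splits, which are too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real splits gave 249, 1103, 4363 and 6431 genes by edgeR, and the highest of the other splits gave 0, with 1471, 4688, 3495 and 265 genes at an unadjusted p under 0.05 for knockdown in untreated cells, knockdown with fulvestrant, fulvestrant in control-vector cells and fulvestrant in knockdown cells. At that unadjusted threshold the real splits had 1525, 3342, 5975 and 7756 genes, so for knockdown with fulvestrant another split had more. For knockdown in untreated cells, the 3 other splits that part every same-numbered pair had 147 to 171 such genes, and the split with 1471 did not part every pair. DESeq2 was not run on the splits.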

How the results depend on the processing

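The GC content correction, the block in untreated cells and the fit without the 4 libraries farthest along the GC trend were chosen after the result was seen. Other settings were planned. Of the gene values under other settings, 4015 kept direction and side of the threshold, 332 lost a call, 36 gained one and 2 turned, and of the list values 2139 kept both, 111 lost and 50 gained a call. With library totals the median log2 fold change of all genes lay between −0.018 and 0.014 in each comparison, against −0.013 to 0.001. The cause was not tested unless stated. Knockdown in untreated cells, knockdown with fulvestrant, fulvestrant in control-vector cells, fulvestrant in knockdown cells and the difference between responses, in that order, gave 34, 106, 439, 1051 and 0 genes with a log2 fold change of at least 1, by construction (edgeR, with 1171 at an unadjusted p under 0.05 for the last). For the last, library totals gave 0 (1005 unadjusted), no filter 0 (1157) and DESeq2 45 (677). With 1 library left out the counts ranged 126 to 319, 456 to 2270, 3102 to 4417, 5165 to 7429 and 0 to 7, lists passing 39 to 48, genes lowered by fulvestrant and higher with knockdown 26 to 68, and correlations of the fulvestrant and knockdown responses 0.57 to 0.74 and 0.18 to 0.45. The extremes came without untreated control-vector library 1 (0.45), 2 (126, 26) or 3 (0.18), fulvestrant-treated control-vector library 1 (0.74), 2 (456, 3102) or 3 (319, 2270, 4417, 7429, 7, 68, 0.57), untreated knockdown library 1 (48) or 2 (5165) or fulvestrant-treated knockdown library 1 (39), and 0 genes for the difference in 10 of the 12 fits. Without the filter, which adds genes with few counts, those correlations were 0.21 and 0.07. The filter was rerun in each fit with 1 library left out, so the tested genes changed there as well. With an estimated correlation 11 list tests passed, against 44: estrogen receptor and p53 targets with knockdown in untreated cells, p53 targets and G1/S with knockdown in treated cells, mevalonate, G1/S and stress with fulvestrant in control-vector cells, G1/S in knockdown cells, and G1/S, NF-kB and stress for the difference. After the GC content correction 30 passed so, these 11 and 19 others. With only the 6 libraries of a comparison the 4 pairwise comparisons, in the order above, gave 255, 229, 2976 and 7036 genes, against 249, 1103, 4363 and 6431. Higher and lower genes of knockdown with fulvestrant were 455 and 433 with library totals and 387 and 359 without the filter, against 672 and 431.

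With the replicate number as a block, knockdown gave 145 (untreated) and 620 (fulvestrant) genes, and the difference between responses 0 (914 unadjusted, DESeq2 45 without block). Over all groups same-numbered libraries did not deviate together (18 pairs, −0.93 to 0.87, 8 above 0.1), and 1 of 12 libraries correlated best with its own number, but the 3 pairs between the untreated groups did. With a replicate block in untreated cells alone, knockdown in untreated cells gave 219 genes, 200 of them among the 249, and the difference 0 (1280 unadjusted). In that comparison of untreated cells the block ended the call of LOXL2 (1.11, adjusted p = 0.108), brought one of ribosomal proteins (−0.04, camera adjusted p = 0.0327) and changed no other call of a named gene or list.

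The GC content correction gave 1007, 3189, 6818 and 8506 genes and 597 for the difference, of which 242, 1040, 4197, 6031 and 4 were among those without it, and 168 genes lowered by fulvestrant and higher with knockdown, with 173 lower in both, against 50 and 23. With that block beside it these were 877, 2978, 6690, 8365, 454, 144 and 134. Without 4 libraries they were 425, 3003, 62 (difference) and 87, with 35 lower in both, with a correlation of fulvestrant responses of 0.65. Leaving out the most distant library of each group narrows the spread within groups by construction, so higher counts there were favoured in advance. MDM2 with knockdown in untreated cells, −0.02, ranged −0.07 to 0.03 with 1 library left out, and was 0.03 and 0.01 without untreated control-vector library 1 or untreated knockdown library 3. At the depth of these libraries (21581887 counts or more) PGR had 0 to 6 counts, at most 0.225 CPM. It lay too near 0 to be tested.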

Other observations

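The GC content correction, the replicate number as a block in untreated cells and the fit without the 4 libraries farthest along the GC trend were chosen after the result was seen. THY1, a surface glycoprotein gene also used as a fibroblast marker, fell from 221 ± 4.1 to 93.3 ± 11 CPM with fulvestrant in control-vector cells and from 244 ± 3.18 to 95.9 ± 13.2 CPM in knockdown cells, while FAP, another fibroblast marker, rose by 0.58 and 1.14 on the log2 scale (edgeR adjusted p-values 1.49e-05, 3.34e-06, 0.00226 and 1.72e-05). The 5 tested fibroblast markers had median log2 fold changes of 0.11 and −0.18 with knockdown (untreated and fulvestrant-treated cells) and −0.53 and −0.83 with fulvestrant (control-vector and knockdown cells), with camera adjusted p-values from 0.374 to 0.592. The 5 mesothelial and endothelial markers had medians of 0.05, −0.21, −0.05 and −0.51 (adjusted p-values 0.177 to 0.478). Among them CALB2, which encodes calretinin, rose with knockdown in untreated cells from 13.7 ± 0.206 to 25.8 ± 0.909 CPM and fell with fulvestrant by 0.78 and 1.14 on the log2 scale, and CDH5 fell by 0.84 with fulvestrant in control-vector cells (adjusted p-values 0.000154, 3.96e-05, 1.09e-06 and 0.000365). The leukocyte list was too small to test, and CD14 had a log2 fold change of −1.80 with fulvestrant in knockdown cells (adjusted p = 0.0143), while CD68 had 0.33 and 0.34 with fulvestrant in control-vector and knockdown cells (adjusted p = 0.0486 and 0.0291), calls lost with the replicate number as a block in all groups or in untreated cells. In control-vector cells that call was also lost without any untreated library of either line, without fulvestrant-treated control-vector library 1 or 2 and in a fit of only the 6 libraries, and in knockdown cells without any untreated knockdown library or fulvestrant-treated knockdown library 1 (adjusted p from 0.0516 to 0.135).

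The receptor tyrosine kinase gene AXL fell by 1.27 and 1.92 on the log2 scale with fulvestrant in control-vector and knockdown cells, and CTGF rose by 1.67 and 1.71, both members of the epithelial-mesenchymal transition list, of which 9 and 10 of 26 rose and 3 and 4 fell, or 9 and 10 rose and 4 and 6 fell adjusted over the list alone (camera adjusted p = 0.252 and 0.311). With knockdown in treated cells 8 rose and 3 fell, or 10 and 4 adjusted over the list alone (median 0.09, camera adjusted p = 0.0462, with adjusted p = 0.438 with an estimated correlation), a call lost without untreated control-vector library 1, fulvestrant-treated control-vector library 3 or fulvestrant-treated knockdown library 1 or 3 (adjusted p up to 0.257). The ovarian transcription factor gene WT1 fell by 0.50 and 0.63 with fulvestrant, beside the rise of MUC16, and the epithelial and ovarian carcinoma list did not pass in any comparison with all libraries and no correction (camera adjusted p 0.128 to 0.941). With knockdown in treated cells it passed after the GC content correction (median 0.12, 7 risen and 0 fallen, camera adjusted p = 0.00432, with adjusted p = 0.028 with an estimated correlation) and without fulvestrant-treated control-vector library 1 or fulvestrant-treated knockdown library 2 (adjusted p = 0.00781 and 0.02). With knockdown in untreated cells it passed without untreated control-vector library 3 or untreated knockdown library 1 (adjusted p = 0.0225 and 0.0352), and with the block and the GC content correction together (0.0489). In the BCL2 family the pro-apoptotic gene BMF rose by 1.63 and 2.01 with fulvestrant, with 4 of 18 risen and 0 fallen in control-vector cells and 6 risen and 3 fallen in knockdown cells, also adjusted over the list alone (camera adjusted p = 0.351 and 0.713). Among hypoxia and glycolysis genes PFKFB3 fell by 0.96 and 1.18 and NDRG1 rose by 0.89 in control-vector cells, and the list did not pass (camera adjusted p 0.258 to 0.919), except with knockdown in treated cells with the block and the GC content correction together (median 0.07, adjusted p = 0.0489). FOSL1, an AP-1 gene, fell from 102 ± 13.6 to 47.4 ± 11.5 CPM and from 93.1 ± 5.57 to 23.3 ± 4.21 CPM, with camera adjusted p-values of the immediate early list of 0.967 and 0.374.

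Transcripts of the mitochondrial genome, a sign of library quality, had medians of 0.23 and 0.31 with knockdown in untreated and treated cells (camera adjusted p-values 0.000419 and 0.000204, with adjusted p = 0.51 and adjusted p = 0.483 with an estimated correlation). With fulvestrant the medians were 0.25 and 0.35 (camera adjusted p-values 0.057 and 0.0318, with adjusted p = 0.723 and adjusted p = 0.721 with an estimated correlation), the last call being lost without fulvestrant-treated knockdown library 1 or 2 or untreated knockdown library 2 (adjusted p up to 0.101) and after the GC content correction (median 0.25, adjusted p = 0.0935), while the list passed in control-vector cells in 6 of the 12 fits with 1 library left out, namely without fulvestrant-treated control-vector library 1 or 2, untreated control-vector library 1, fulvestrant-treated knockdown library 3 or untreated knockdown library 1 or 2, and also without the low count filter, without the 4 libraries farthest along the GC trend, and with the replicate number as a block in all groups, in untreated cells, or in untreated cells with the GC content correction (adjusted p from 0.00839 to 0.0491). Their share of the counts was 0.19% to 0.31% per library. Replication-dependent histones, most of which lack poly(A) tails, had medians of −0.65 and −0.98 with knockdown (camera adjusted p-values 1.03e-05 and 0.00991, with adjusted p = 0.359 and adjusted p = 0.646 with an estimated correlation) at a median level of 1.51 CPM in untreated control-vector cells. The histone call in treated cells was lost without fulvestrant-treated control-vector library 1 or fulvestrant-treated knockdown library 2 (adjusted p up to 0.106) and after the GC content correction (median −1.06, adjusted p = 0.0815). Steroid receptors and coregulators had a median of 0.21 with fulvestrant in knockdown cells, with 11 of 22 risen and 1 fallen, also adjusted over the list alone (camera adjusted p = 0.048, with adjusted p = 0.227 with an estimated correlation), a call lost without any fulvestrant-treated control-vector library, untreated control-vector library 2, fulvestrant-treated knockdown library 1 or 2 or untreated knockdown library 2 (adjusted p up to 0.0777). The coactivator genes NCOA1 and NCOA2 rose by 0.67 and 0.53 there. Mevalonate genes had a median of −0.06 with knockdown in untreated cells (camera adjusted p = 0.0478, with adjusted p = 0.379 with an estimated correlation), a call lost without untreated or fulvestrant-treated control-vector library 1 or 2, fulvestrant-treated knockdown library 1 or 2 or untreated knockdown library 3 (adjusted p up to 0.167), and with the block and the GC content correction together (adjusted p = 0.0541). Ribosomal proteins had a median of −0.04 with knockdown in untreated cells (camera adjusted p = 0.0865), and passed without untreated control-vector library 3 or untreated knockdown library 1 or 2, after the GC content correction, without the 4 libraries farthest along the GC trend, and with the block in untreated cells alone or with that correction (adjusted p from 0.00268 to 0.0451). Of 48 ribosomal protein genes 11 rose and 0 fell with fulvestrant in knockdown cells, or 8 and 0 adjusted over the list alone (median 0.10, camera adjusted p = 0.177). G1/S genes had a median of −0.10 with knockdown in untreated cells with no member past the edgeR threshold (camera adjusted p = 0.000152, with adjusted p = 0.181 with an estimated correlation), and stress response genes one of 0.09 (camera adjusted p = 0.00129, with adjusted p = 0.0628 with an estimated correlation). There 8 G1/S genes were lower and 8 stress response genes higher after the GC content correction, with adjusted p = 0.0197 and adjusted p = 0.0606 with an estimated correlation.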
